A study of Homo sapiens with 4 samples.

How the data were processed

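Conditioned media of U937 cells, a human myeloid leukaemia line of monocytic character, were profiled on a protein array with a biotin label. Per the labels' protocols, the cells carried either an empty retroviral vector or 1 of a pair of dominant negative fragments of TIFA (an adaptor protein of innate immune signalling), named F1F2 and F2F3. Equal numbers of cells were treated with 10 µM cytarabine, a nucleoside analogue that blocks DNA synthesis, for 72 h, and cell-free supernatant was collected after centrifugation. The dose and time of the PBS sample are not given in the sources used here. There are 4 samples, each the only one of its group: vector with PBS, vector with cytarabine, F1F2 with cytarabine and F2F3 with cytarabine. The series' design text names F1F2 for both fragment samples, whereas the title and source of the last sample name F2F3; the sample's own labels were followed.

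The authors deposited 1 table of intensities, with 23 protein rows and 2 control rows for the 4 samples. In the deposited intensities the negative control is 0 and the positive control is 1 on every array, and 13 of the 92 protein values are below 0. The intensities were therefore read as linear signals after background subtraction, relative to the positive control. How the spots were scanned, whether replicate spots were averaged, and which array and software were used are not given in the sources used here. A protein array has no read depth; the precision is limited by 1 array per group, and the error of each value is unknown. The highest value was 1.47, above the positive control; whether such signals lay in the linear range is not known.

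The rows named TGF-beta and TNF-beta hold identical values in all 4 samples. It is not known to which protein they belong, so both were left out, which leaves 21 proteins; they enter only the percentile that sets the floor and the alternatives that name them. Protein names are those of the table; the 24 gene symbols assigned to the 23 rows by name were all found in a table of human genes. The name GRO was taken as that of the GRO chemokine family (CXCL1, CXCL2 and CXCL3), and GRO-alpha as CXCL1.

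With 1 sample per group there is no test, and no p-value or standard error is given. For each protein the log2 ratio of the 2 intensities was computed, and a protein was called higher or lower from a ratio of 1.5-fold. Some values lie at or below 0 and have no logarithm, which the design fixed earlier had not foreseen. Values under the 25th percentile of all protein values, 0.0099, were raised to it, and a fold against such a value is a lower bound ("at least"). Where both values lay under it, the protein was counted as low signal and given no fold. Scaling between arrays was left as deposited. Proteins reaching 0.1 in one of the samples compared are called bright below, a limit set after the values were seen.

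Fixed before the data were examined were the 3 comparisons, the threshold, the rule for named proteins and 7 protein lists: NF-kB targets, chemokines, myeloid pro-inflammatory cytokines, leaderless or stored proteins, colony-stimulating and growth factors, anti-inflammatory proteins, and lymphocyte cytokines as markers of another cell type. Up to 30 proteins per comparison were to be named by size of change among those past the threshold with at least 1 value at or above the 25th percentile, and any protein of so small a panel for its place in a list. A list's median log2 ratio was taken where 3 members or more had a ratio. Its percentile was found among 10000 random lists of the same size, matched on mean signal in 3 bins, and describes these samples only. The random lists were drawn from all proteins with a ratio, list members included. A list that fills most of a bin is thus compared largely with itself, and its percentile is no comparison with a background.

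Both fragments were compared with the same vector sample. The overlap of their calls was set beside that of independent lists and beside 10000 simulated tables without any effect, in which each array had an independent error of 0.54 (SD, log2), the size that would produce as many calls by error alone. The ratio code was tested on simulated data, 200 tables of 21 proteins with 3-fold changes and no added error. It recovered the changes put in, which checks the arithmetic only and gives no error rate. Alternatives were scaling of each array to the same median or total, other thresholds, a filter on dim proteins, counting of the identical rows, mean list values and lists with each member left out. A pseudocount at the 10th percentile was planned, but that percentile was below 0; a pseudocount of 0.05, no floor, bright proteins only, and a median over all 23 rows in place of the 21 proteins were added after seeing the data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.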

Results

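Intensities of 21 distinct proteins were compared in conditioned media of U937 cells, with 1 array for each of 4 conditions. Every value below is a single measurement (n = 1), so no difference could be set against a spread between replicates. All values are intensities relative to the positive control spot. Of the 21 proteins, 9 reached 0.1 in at least 1 sample. These were IL-6, TNF-alpha, GRO, IL-8, MCP-1, MCP-2, IL-10, RANTES and IL-5. IL-13, IL-15 and G-CSF lay under the floor of 0.0099 in every sample. The 8 proteins that stayed under 0.05 in all samples ranged over 0.0121 to 0.0339 between the samples, with a median range of 0.018, so folds of such dim proteins rest on differences of that order. The summed intensity of the 21 proteins was 4.24 in the vector sample with PBS and 4.35 in the vector sample with cytarabine. It was 3.91 in the F1F2 sample and 3.67 in the F2F3 sample.

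**Figure D1:**
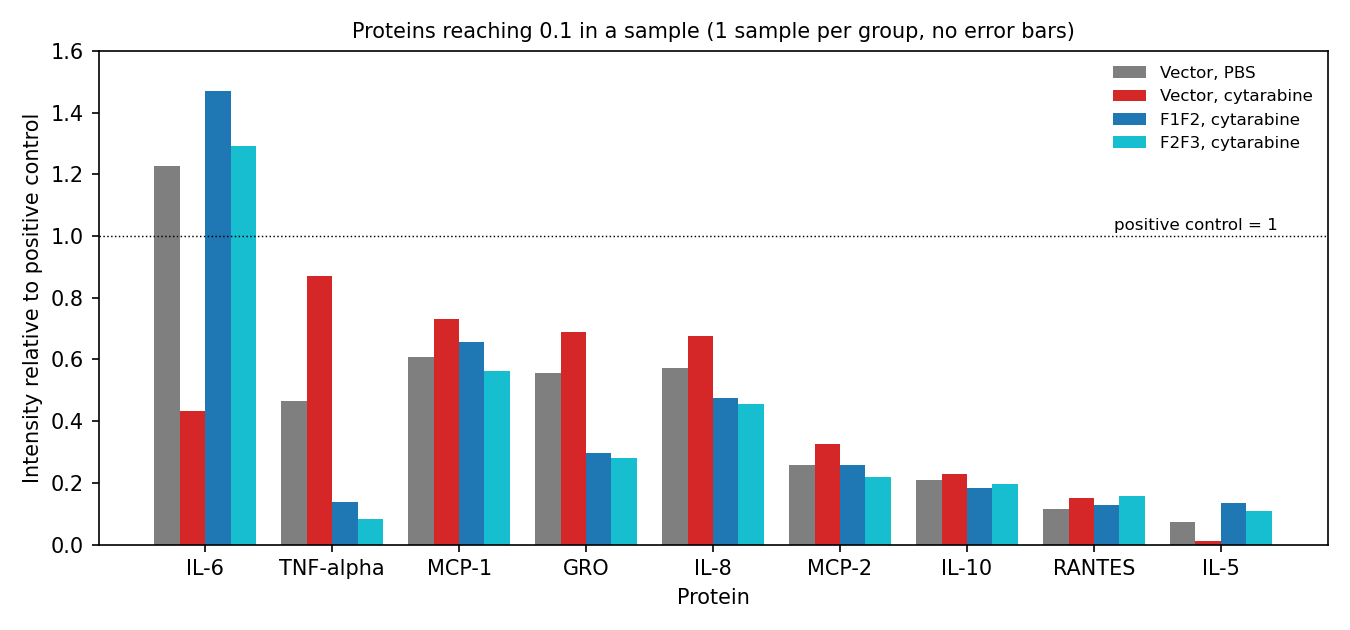
Intensity relative to the positive control (vertical axis, no unit) of the 9 proteins that reached 0.1, with 1 bar per sample and no error bars because each group has 1 array. TNF-alpha was highest in the vector sample with cytarabine (0.871) and lowest in the F2F3 sample (0.0824), whereas IL-6 was lowest in the vector sample with cytarabine (0.431).

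The first comparison set the medium of vector cells with cytarabine beside that with PBS. No value here was corrected for the number or viability of cells at collection, so the intensities describe the medium and not release per cell. This holds for the comparisons with the fragments too. TNF-alpha, the inflammatory cytokine that activates NF-kB through its receptors, was 1.87-fold higher with cytarabine, at 0.871 against 0.467 with PBS. IL-6, a cytokine of the acute phase response, was 2.84-fold lower, at 0.431 against 1.23. The 5 bright chemokines were higher by less than the 1.5-fold threshold: RANTES (CCL5) by 1.28-fold, MCP-2 (CCL8) by 1.27-fold, GRO by 1.24-fold, MCP-1 (CCL2) by 1.20-fold and IL-8 (CXCL8), which attracts neutrophils, by 1.18-fold. IL-10, an anti-inflammatory cytokine, was 1.09-fold higher. Of the 8 bright proteins, 7 had a higher value with cytarabine and 1, IL-6, a lower one.

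Among the dim proteins, GRO-alpha (CXCL1) was at least 6.14-fold higher with cytarabine, with 0.0608 against 0.00224. IL-3, a growth factor of blood progenitors, was 1.69-fold higher, from 0.0193 to 0.0328. IL-5, an eosinophil growth factor, was 6.02-fold lower, at 0.0123 against 0.0741. IL-7 was 2.15-fold lower, at 0.0162 against 0.0347. IL-1-beta was 1.75-fold lower, at 0.00993 against 0.0174, which puts it at the floor. In all, 3 proteins were higher and 4 lower among the 17 with a ratio. Only TNF-alpha and IL-6 of these 7 were bright in this comparison.

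Of the 10 proteins in the NF-kB target list, 9 had a ratio with cytarabine: 2 were higher (TNF-alpha and GRO-alpha), 2 were lower (IL-6 and IL-1-beta) and 5 did not pass the threshold. GM-CSF, a member, was 0.0634 with cytarabine and 0.0468 with PBS. The list's median log2 ratio was 0.31, at the 72.4th percentile of random lists matched on signal. The 7 chemokines with a ratio had the same median, 0.31, at the 66.7th percentile, with 1 higher and none lower. Both medians are the ratio of GRO, a member of both lists, so they are 1 value. Each list fills most of the brightest bin, so neither percentile is a comparison with a background. The eighth chemokine, MIG (CXCL9), was of low signal. The 3 myeloid pro-inflammatory cytokines, IL-1-beta, IL-6 and TNF-alpha, went both ways, with a median of -0.81 at the 8.25th percentile, which is the ratio of IL-1-beta, near the floor. Of the lymphocyte cytokines, IL-5 was lower, IFN-gamma was 0.0328 in both vector samples, IL-2 was 0.0131 with cytarabine and -0.000412 with PBS, and IL-13 was of low signal; the median of the 3 with a ratio was -0.0026, at the 29.4th percentile.

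The next comparisons asked how either dominant negative TIFA fragment changed the medium under cytarabine, relative to vector cells given the same drug. TNF-alpha had the lowest ratio to vector of the 9 bright proteins with either fragment. It was 6.35-fold lower with F1F2 (0.137) and 10.6-fold lower with F2F3 (0.0824) than with vector (0.871). GRO was 2.33-fold lower with F1F2 (0.296) and 2.46-fold lower with F2F3 (0.280) than with vector (0.689). IL-6 differed in the opposite direction, being 3.41-fold higher with F1F2 (1.47) and 2.99-fold higher with F2F3 (1.29). IL-5 was higher too, by 10.9-fold with F1F2 (0.134) and by 8.97-fold with F2F3 (0.110); its signal was 2.85% to 9.09% of that of IL-6 in the 4 samples. These directions were the same when arrays were scaled to the same median or the same total.

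The remaining bright proteins did not reach the threshold in either comparison as deposited, but all 5 did, as lower with both fragments, when arrays were scaled to the same median over the 21 proteins. IL-8 was 1.42-fold lower with F1F2 and 1.48-fold lower with F2F3. MCP-2 was 1.26-fold lower with F1F2 and 1.48-fold lower with F2F3. MCP-1 was 1.11-fold lower with F1F2 and 1.29-fold lower with F2F3. IL-10 had a log2 ratio of -0.32 with F1F2 and -0.23 with F2F3, a direction that turned for F2F3 when arrays were scaled to the same total. RANTES was 1.16-fold lower with F1F2 and 1.04-fold higher with F2F3, and lower for both when arrays were scaled to the same median. Under that scaling the log2 ratios with F1F2 and F2F3 were -1.04 and -1.24 for IL-8, -0.87 and -1.24 for MCP-2, -0.69 and -1.04 for MCP-1, -0.85 and -0.90 for IL-10, and -0.75 and -0.61 for RANTES. Under scaling to the same total none of these 5 passed it.

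Among the dim proteins, GRO-alpha was at least 6.14-fold lower with F1F2 (-0.00458) and 3.21-fold lower with F2F3 (0.019) than with vector (0.0608). IL-7 was 2.33-fold higher with F1F2 (0.0377) and 3.23-fold higher with F2F3 (0.0523). MCP-3 (CCL7) was at least 2.15-fold higher with F1F2 (0.0213) and at least 3.74-fold higher with F2F3 (0.0371), against 0.00313 with vector. IFN-gamma passed the threshold with F2F3, at 1.73-fold (0.0568), and was 1.44-fold higher with F1F2 (0.0474). Scaling to the same median ended this call, with a log2 ratio of 0.12 against 0.79 as deposited, and scaling to the same total gave 0.68 with F1F2, past the threshold. MIG was at least 1.73-fold higher with F2F3 (0.0172) and at least 1.16-fold higher with F1F2 (0.0115), and its call with F2F3 also ended under median scaling (log2 ratio 0.24, and -0.12 with F1F2). In all, 4 proteins were higher and 3 lower with F1F2, and 6 were higher and 3 lower with F2F3, among 18 with a ratio in each comparison. The share of higher calls was thus 57.1% with F1F2 and 66.7% with F2F3. It was 28.6% with either fragment when arrays were scaled to the same median, with 4 higher and 10 lower for each. That scaling shifted the log2 ratios to vector by -0.53 for F1F2 and by -0.67 for F2F3. Scaling to the same total shifted them by 0.15 and 0.25, with 62.5% and 66.7% of calls higher.

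Of the 9 NF-kB targets with a ratio, 3 were lower with either fragment (TNF-alpha, GRO and GRO-alpha), 1 was higher (IL-6) and 5 did not pass the threshold. By the symbols assigned, GRO and GRO-alpha overlap in CXCL1, so they are not independent targets here or among the chemokines. The median log2 ratio was -0.35 with F1F2, at the 8.16th percentile of matched random lists, and -0.37 with F2F3, at the 45.3rd percentile. NF-kB targets fill most of the brightest bin, so these random lists repeat many of the list's own members. The percentiles therefore set the list neither against a background nor apart between the fragments. Scaled to the same median, 7 targets were lower with either fragment. GM-CSF, which did not pass as deposited, was 1.28-fold lower with F1F2 and 1.26-fold lower with F2F3. G-CSF was of low signal in all samples. Of the 8 chemokines, 2 were lower with either fragment (GRO and GRO-alpha), 1 was higher with F1F2 (MCP-3) and 2 with F2F3 (MCP-3 and MIG). Their median was -0.28 with F1F2, at the 38.5th percentile, and -0.47 with F2F3, at the 21.4th percentile. Chemokines fill most of the brightest bin too, so these percentiles have the same limit. Scaled to the same median, 6 chemokines were lower with either fragment.

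The 3 myeloid pro-inflammatory cytokines held 1 higher (IL-6), 1 lower (TNF-alpha) and 1 that did not pass (IL-1-beta) with either fragment. Their median was the ratio of IL-1-beta. With F1F2 the floor sets that ratio near 0, so no median is given. With F2F3 it was 0.45, at the 86.1st percentile, while the mean of -0.46 had the opposite sign and the median itself turned to -0.22 when arrays were scaled to the same median. The lymphocyte cytokines with a ratio had a median of 0.53 with F1F2, at the 77.1st percentile, and 0.79 with F2F3, at the 67.2nd percentile. These are the ratios of IFN-gamma, and the F2F3 value was 0.12 when arrays were scaled to the same median, while the F1F2 one is then fixed at no change because IFN-gamma is the median protein of both arrays. IL-2 was -0.00462 with F1F2 and 0.00782 with F2F3, both under the floor. The other lists had fewer than 3 members with a ratio. IL-3 had a log2 ratio of 0.32 with F1F2 and 0.26 with F2F3 as deposited. With arrays scaled to the same median it turned to -0.21 with F1F2 and -0.41 with F2F3. IL-1-beta, the only leaderless protein measured, was -0.00153 with F1F2 and 0.0136 with F2F3, against 0.00993 with vector. IL-10 was the only anti-inflammatory protein with a ratio.

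Both fragment samples were called alike for 7 proteins. IL-5, IL-6, IL-7 and MCP-3 were higher in both. TNF-alpha, GRO and GRO-alpha, which overlaps GRO in CXCL1, were lower in both. Independent lists of these sizes would share 1.33 higher and 0.5 lower proteins. Because both ratios have the same vector sample as control, simulated tables without any effect shared 1.84 higher and 1.81 lower proteins on average, and the upper limit of these simulations was 5 in each direction. The log2 ratios of both fragments correlated across the 18 proteins with r = 0.96, though proteins are not independent replicates, and the simulation gave a mean of 0.487 with an upper limit of 0.791. The covariance was 2.03, against a simulated 0.291 with an upper limit of 0.630. The simulation gave every array an error of the same size for every protein. A larger error of the shared vector array would raise both values, so values above these limits do not show agreement beyond the shared control. How much of the agreement comes from that control cannot be told, because it is 1 array.

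**Figure D2:**
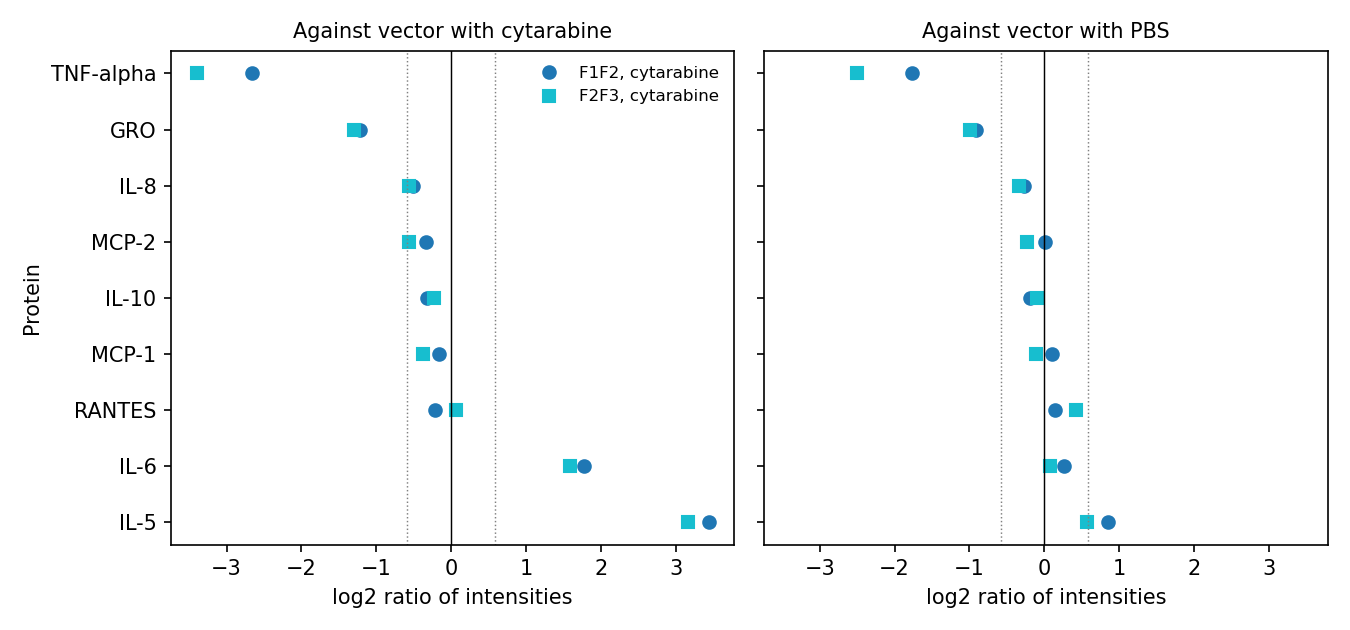
Log2 ratio of intensities (horizontal axis) of the 9 bright proteins in the F1F2 sample (circles) and the F2F3 sample (squares), against the vector sample with cytarabine (left) and against the vector sample with PBS (right), 1 array per sample; dotted lines mark 1.5-fold. TNF-alpha and GRO lay left of the dotted line in both panels, while IL-6 lay near 0 against PBS (0.26 and 0.08).

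Against the vector sample with PBS, TNF-alpha was 3.40-fold lower in the F1F2 sample and 5.66-fold lower in the F2F3 sample. GRO was 1.88-fold lower with F1F2 and 1.99-fold lower with F2F3. The dim GRO-alpha, which overlaps GRO in CXCL1, was of low signal with F1F2 and PBS. With F2F3 it was at least 1.92-fold higher than with PBS, at 0.019 against 0.00224. IL-6 was within 1.20-fold of the PBS sample with F1F2 and within 1.05-fold with F2F3. IL-5 was 1.81-fold higher with F1F2 and 1.49-fold higher with F2F3. The other 5 bright proteins did not reach 1.5-fold in either sample. All these ratios to PBS are as deposited, and calls near the threshold depend on that. Scaling to the same median multiplies the PBS, F1F2 and F2F3 arrays by 1.20, 0.88 and 0.80, which lowers the ratios. Scaling to the same total multiplies them by 0.95, 1.03 and 1.10, which raises the ratios. Fragment cells without cytarabine were not analysed here, so the effect of the drug in those cells was not measured.

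Between the fragments, TNF-alpha was 1.66-fold higher with F1F2 than with F2F3, the only bright protein of 9 to pass the threshold. GRO-alpha was at least 1.92-fold lower and MCP-3 1.74-fold lower with F1F2. IL-6 was 1.14-fold higher and GRO 1.06-fold higher with F1F2. With 1 array of each, no interval can be given for these differences.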

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

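All tests in this part were chosen after the values were seen. RANTES differed in direction between the fragments against the vector sample with cytarabine, with a log2 ratio of -0.21 for F1F2 and 0.063 for F2F3; the difference was not tested, as each is 1 array. The row deposited under both TGF-beta and TNF-beta, left out of the protein ratios, read 0.0198 in the vector sample with cytarabine against 0.00764 with PBS, 0.0158 with F1F2 and 0.0143 with F2F3, all within the range of dim proteins.

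TNF-alpha and GRO were lower in both fragment media than in vector medium under cytarabine. A vector array that happened to read high for these proteins would leave the fragment samples at the PBS level. They lay below it, with log2 ratios to PBS of -1.77 or lower for TNF-alpha and -0.91 or lower for GRO. The 6 proteins other than GRO at or above 0.1 in all samples ranged from -0.33 to 0.42. TNF-alpha with F2F3 and IL-5 with vector were under 0.1, and IL-5 had 0.85 with F1F2 and 0.58 with F2F3. For TNF-alpha these values argue against that array as the whole cause. For GRO they do so less, since IL-5 lay nearly as far from PBS. GRO-alpha, near the floor, read 0.00224 with PBS, -0.00458 with F1F2 and 0.019 with F2F3, so it was not below PBS with F2F3. Less protein in the fragment media, or dimmer arrays, would lower the other proteins as much if all signals were linear, which is not known. The median log2 ratio to vector with cytarabine of the same 6 proteins was -0.27 for F1F2 and -0.30 for F2F3. IL-5, not among them, was higher with both. What stays open is an effect of the fragments on these proteins, a difference between separately selected cell lines that also exists without the drug, and error of single arrays. A different number or viability of cells at collection, which was not corrected for, stays open too. The design tells none of these apart.

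IL-6 was lower in the vector sample with cytarabine than in the 3 other samples. A dimmer array overall is argued against, since the lowest log2 ratio to PBS among the other bright proteins was 0.13, in the direction of higher signal. A low IL-6 reading on that array alone cannot be told apart from a drug effect that both fragments remove. Either would leave the fragment samples near the PBS sample. The largest difference from it was 0.26 in log2 as deposited. How near they lie depends on the scaling, since the same median lowers the ratios to PBS and the same total raises them. The opposite changes of IL-6 with cytarabine and with the fragments therefore rest on 1 value, 0.431.

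IL-5, an eosinophil growth factor that lymphocytes release, followed IL-6: it was lowest in the vector sample with cytarabine and highest with F1F2. A candidate explanation is that part of the bright IL-6 signal was read at the IL-5 position. IL-5 was not a constant percentage of IL-6, at 2.85% in vector with cytarabine and 6.04% in vector with PBS. The test used a line through both vector samples, with a slope of 7.77% of the change in IL-6 and a free offset. This line left an excess of 0.0407 with F1F2 and 0.0313 with F2F3. Both were close to the largest range of dim proteins (0.0339), so the test did not decide. That range is the difference of MCP-3 between the F2F3 sample and vector with cytarabine, called as higher above. It is therefore no clean measure of error. The positions of the spots are not given in the sources used here, and IL-6 exceeded the positive control in 3 samples, where a share need not be fixed.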

How the results depend on the processing

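With 1 array per group no replicate could be left out, and no paired analysis was possible because each group has a single sample. The table is already scaled to its positive control, so that scaling was not run again, and the planned pseudocount was not run because it was below 0. The pseudocount of 0.05, the ratio without a floor, the median over all 23 rows and the restriction to proteins reaching 0.1 were chosen after seeing the data. Of 178 alternative values for the counts and for the NF-kB and chemokine list medians, 151 stayed within the limits set and 27 moved. The limits were 1.5 times for a count and the looser fold threshold for a median. The label of reversed was given to 0. It could not arise for a count, or for a median smaller in size than the looser threshold, so it is no sign of stability. The other lists are not among these values, and the myeloid median with F2F3 turned, as given above. Scaling to the same median over the 21 proteins gave 10 lower proteins with F1F2, 10 with F2F3 and 10 with both, and list medians of -0.88 with F1F2 and -1.04 with F2F3 for NF-kB targets and of -0.81 and -1.14 for chemokines. By its construction it rests on proteins near background, with medians of 0.0328 to 0.0523. With all 23 rows, the identical pair included, it gave 7 lower with F1F2, 8 with F2F3 and 7 with both, and list medians with F2F3 of -0.99 for NF-kB targets and -1.09 for chemokines. The looser planned threshold gave 7 higher with cytarabine, 7 lower with F1F2, 8 lower with F2F3 and 7 lower with both, and the 2-fold threshold gave 1 higher with cytarabine. Counting the identical rows separately gave 5 higher with cytarabine. The pseudocount gave 2 lower with cytarabine, 2 higher with F1F2, 3 higher with F2F3 and 2 higher with both. Proteins reaching 0.1 alone gave 1 higher and 2 lower with cytarabine, and 2 higher with F1F2, with F2F3 and with both. TNF-alpha, GRO, IL-6 and IL-5 kept their direction under both scalings; with F2F3 scaled to the same median their log2 ratios were -4.07, -1.97, 0.91 and 2.49. Leaving out single members gave NF-kB medians of 0.28 to 0.33 with cytarabine, -0.43 to -0.28 with F1F2 and -0.47 to -0.35 with F2F3. Folds of dim proteins rest on signals near background.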

Other observations

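The bright proteins of both fragment media lay nearer to the vector sample with PBS than to the vector sample with cytarabine, on the log2 scale, for 9 of 9 proteins with F1F2 and 8 of 9 with F2F3, the exception being RANTES. Scaled to the same total the counts were 7 of 9 with either fragment, the exceptions being MCP-1 and RANTES with F1F2 and IL-10 and RANTES with F2F3, and scaled to the same median they were 9 of 9 with both. An error of the vector array with cytarabine alone would give the same count, so it does not separate that array from the drug. IL-3, a dim protein, was lowest in the vector sample with PBS (0.0193) and lay between 0.0328 and 0.0409 in the 3 samples with cytarabine.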
